A study of Homo sapiens with 10 samples.

How the data were processed

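RNA-seq libraries of human CD14+ monocytes were analysed, 5 from cells given vehicle (PBS) and 5 from cells given recombinant galectin-1 (rGal-1) at 5 µg/mL, each for 7 h. Per the labels' protocols, monocytes of patients with myeloproliferative neoplasms were enriched with magnetic beads, total RNA was purified on columns with a DNase step, and cDNA made from nanogram amounts of RNA with an amplification kit was sheared, ligated to adapters and amplified by PCR. A poly(A) selection or ribosomal RNA depletion is not given in the sources used here. The authors deposited raw read counts per gene symbol, whole numbers with no normalisation. Per the submitters' processing notes, bcl2fastq, STAR, Subread, featureCounts and Salmon were used with the GRCh38 build; the notes give these tools no role or order. The annotation release and strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies could not be told apart. No molecular identifiers were described, so amplified copies of a molecule were counted as separate reads.

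The table held 59653 genes, of which 19239 had no count in any library, and 55022 symbols matched GENCODE release 29. Total counts per library ran from 19549215 to 39511161, and counts outside the mitochondrial genome from 1204936 to 8366187. In the shallowest library after scaling, a count of 0 allows up to 0.329 CPM (counts scaled to a common library size), the level of 3 counts. Binomial intervals and this limit cover counting error only. The libraries of each arm were compared for duplicates over genes with at least 20 counts in a pair of libraries: the chi-square statistic per degree of freedom was at least 71.7 in the 10 PBS comparisons and at least 104 in the 10 rGal-1 comparisons, so no library was a copy of another in its arm; libraries of different arms were not compared in this way.

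Samples were grouped by their treatment label. The titles carry the same 5 numbers in both arms, and the numbered pairs are called A to E here. The labels do not state that a number marks a patient, so the numbers were checked in the data. Deviations of log2 CPM from the arm means correlated across genes between the libraries of a number by 0.63, 0.51, 0.28, 0.36 and 0.61 in pairs A to E, each above the minimum of 0.1 set for using the pairing, and each library correlated best with its own number. Correlations with another number reached 0.29 between pairs D and E and 0.20 between pairs B and C. Passing the minimum of 0.1 thus does not by itself tell pairs apart, and the margin was small in pairs C and D. Nothing says that libraries of an arm came from separate donors, so p-values measure the spread between these samples.

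Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust dispersions, TMM scaling, filterByExpr with a minimum count of 10), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Filtering left 12629 genes. A fit without a block and a fit with the pair number as a block (6 and 321 genes called) were both set before the data were examined, with the rule that the second supplies the values of named genes and the counts per list if the pairing check passes. Fold changes are log2 of rGal-1 over PBS with the standard error (SE), from the fit with the block. Levels are TMM-scaled CPM computed from the deposited counts, as mean ± standard deviation (SD) over the 5 libraries of an arm. The library sizes include mitochondrial counts, so CPM is not relative to nuclear counts alone. The TMM factors ran from 0.253 in rGal-1 library C to 2.93 in PBS library B. For log2 CPM a prior count of 2 was used. Also set before the data were examined were 34 gene lists, tested with camera in limma 3.58.1 on log2 CPM with the block and a preset correlation of 0.01, adjusted over the lists. Library measures were compared by a two-sided exact sign-flip test over the 5 pairs, which cannot give a p under 0.0625.

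Named genes were drawn by a rule: LGALS1, then the 12 largest and 12 smallest fold changes among genes with a symbol that passed the test, had a mean log2 CPM of at least 0 and moved the same way in all 5 pairs, and the 4 members of each list with the smallest p. Y-linked genes, XIST and antigen receptor segments were left out of this naming. IL1B, TNFSF14 and CCL3 were named after their values were seen, as were PLBD2, CTSD, CTSB, ATP6V1C1, CYP1A1, AHRR, C5AR1 and CCR1 and the lists of the closing section they belong to. Of the 130 genes drawn from the lists, 42 passed the test; the 88 that did not pass are named in part and otherwise given only in the counts of their list. Of the added lists 1, and of the 42 genes 1, is not reported here. Coordinates are 1-based, from GENCODE release 29 on GRCh38.

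The fits were tested on counts simulated from these libraries with known changes, over 11163 genes. With the pair block, 13 of 100 changes of 1 on the log2 scale and 90 of 93 changes of 3 were recovered, and 1 of 104 calls was false. Without the block, 0 of 100 and 48 of 93 were recovered. The counts were drawn gene by gene from the fit with the block, which favours that fit. The changes were placed in genes with a mean CPM of at least 1. Correlation between genes was left out, so the false calls need not match those of the real counts. Alternatives were DESeq2 size factors, no filter on low counts, a CPM of at least 1 in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, the pair as a random effect, an adjusted p under 0.1, a test against a log2 fold change of 0.5, camera with an estimated correlation, fry, and leaving out each pair and each library. Leaving out mitochondrial genes, leaving out pairs C and D, whose libraries were over 90% mitochondrial, and dispersions without the robust option were alternatives chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.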

Results

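The series asked how galectin-1, a secreted lectin that binds galactosides, acts on inflammatory monocytes in myeloproliferative neoplasms, a group of clonal blood disorders. RNA was sequenced from 5 libraries of bead-enriched CD14+ monocytes kept with PBS and 5 kept with rGal-1, in numbered pairs A to E. Total counts ranged from 19549215 to 39511161 per library. Most counts came from the mitochondrial genome, whose ribosomal RNA genes alone held a mean of 66.1% of all counts with PBS and 66.3% with rGal-1. The share of the whole mitochondrial genome was 84.9% ± 10.2 (SD, n = 5) with PBS and 86.0% ± 10.5 (SD, n = 5) with rGal-1. The mean difference within pairs was 1.14 percentage points ± 6.01 (SD), with a higher share after rGal-1 in 4 of 5 pairs (exact sign-flip test, p = 0.5625, n = 5), within the spread between pairs. The libraries of pairs C and D had shares of 94.0% to 96.7% and nuclear counts of 1204936 to 2370423, against nuclear counts of 3895489 to 8366187 in pairs A, B and E, so the fold changes of C and D rest on fewer counts.

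**Figure D1:**
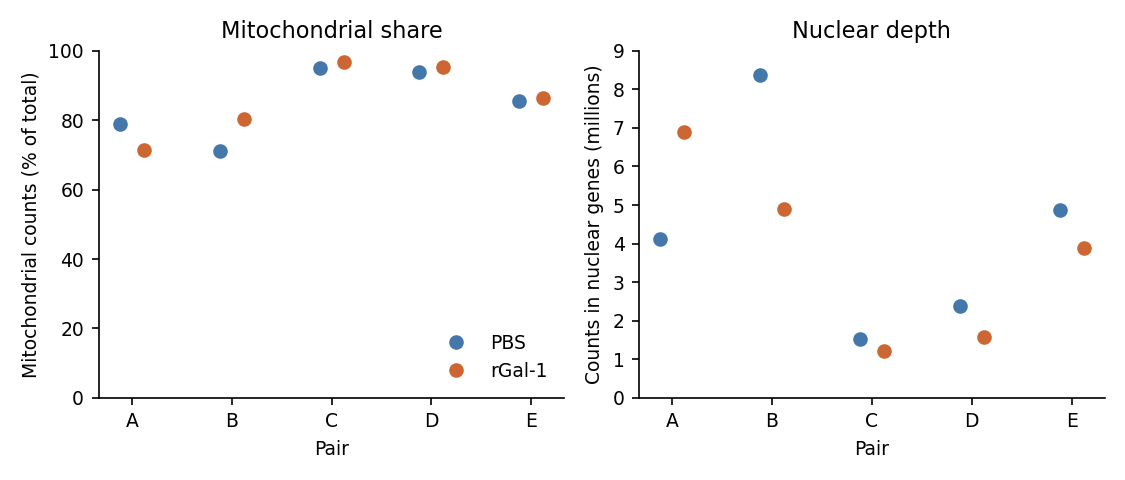
Mitochondrial share of all counts (%) and counts in nuclear genes for each library, by pair and treatment. The 4 libraries of pairs C and D have shares of 94.0% to 96.7% and the lowest nuclear counts, 1204936 to 2370423.

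After rGal-1 some cytokine and chemokine genes had more RNA, and some genes of lipid handling had less. IL6, an acute-phase cytokine, had the largest fold change of the genes called, 6.84 ± 0.49 (SE) on the log2 scale, from 0.396 ± 0.593 CPM with PBS to 32.9 ± 26.7 CPM with rGal-1 (SD, n = 5, adjusted p = 5.93e-06). IL6 was higher in 5 of 5 pairs, and 2 PBS libraries held no IL6 read. Among the named genes GPNMB, a transmembrane glycoprotein of macrophages, fell furthest, at -5.26 ± 0.49 (SE), from 60.3 ± 60.5 CPM with PBS to 1.74 ± 2.62 CPM with rGal-1 (SD, n = 5, adjusted p = 6.78e-05). Within pairs 321 of 12629 genes passed the test, 135 higher and 186 lower, of which 298 moved the same way in all 5 pairs. Their absolute log2 fold changes ran from 0.91 to 6.84, with a median of 1.74.

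Without the pair block 6 genes passed, 0 higher and 6 lower, all among the 321. That fit had 534 genes at an unadjusted p under 0.05, against 631 expected by chance, and the fit with the block had 1883; DESeq2 without the block called 55 genes, 15 higher and 40 lower. Of 85 genes examined singly, 72 lost their call without the block, among them IL6 (adjusted p = 0.0994) and GPNMB (adjusted p = 0.153). With the block the count was 77 without pair B and 99 without pair E, 100 and 106 without the PBS or the rGal-1 library of pair B, 128 and 110 without those of pair E, and 207 without the PBS library of pair D. Without pairs C and D it was 425, 282 higher and 143 lower. With DESeq2 size factors the split was 150 higher and 136 lower, and the median log2 fold change of all genes moved from -0.02 to 0.08.

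**Figure D2:**
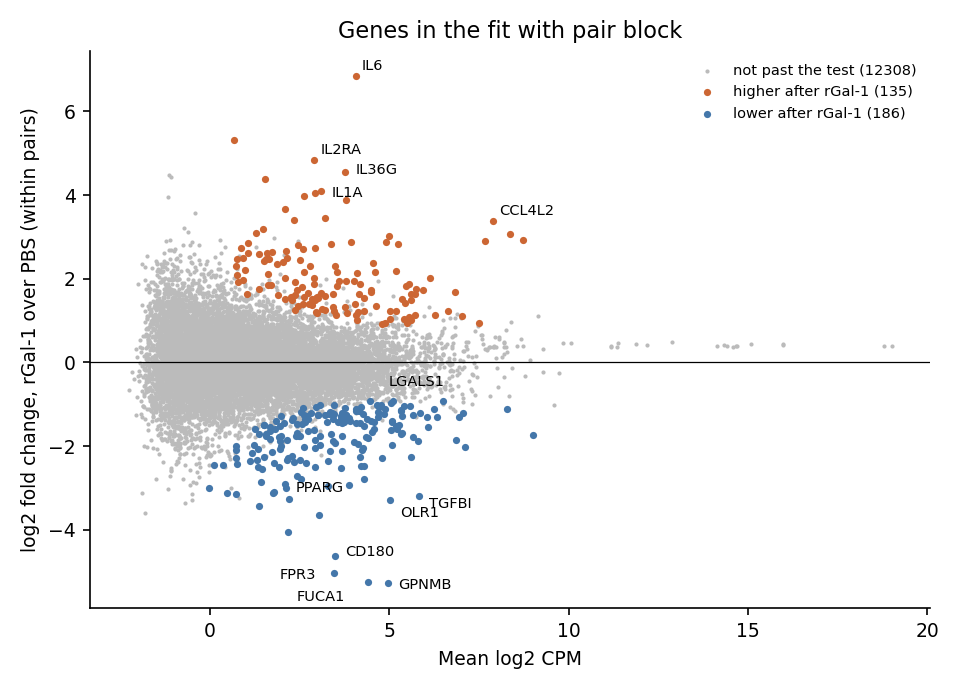
Log2 fold change of rGal-1 over PBS within pairs against mean log2 CPM for the 12629 genes tested. The 135 genes called higher and 186 called lower are coloured and reach 6.84 at IL6.

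Among the named genes that rose, IL2RA, a chain of the interleukin-2 receptor, had a log2 fold change of 4.84 ± 0.73 (SE, adjusted p = 0.00303). IL36G, a cytokine of the interleukin-1 family, rose by 4.55 ± 0.66, IL1A by 4.10 ± 0.45, and ACOD1, which makes itaconate in activated macrophages, by 4.04 ± 0.78. The non-coding transcripts LINC00158 and MIR3945HG rose by 4.38 ± 0.73 and 3.89 ± 0.50. No LINC00158 read was in 3 PBS libraries. GCKR, C1QTNF1 and ETV3L rose by 3.45 ± 0.63, 3.40 ± 0.58 and 3.19 ± 0.51. IL36G, IL1A, ACOD1, MIR3945HG, C1QTNF1 and ETV3L had no read in 1 PBS library each. The chemokine genes CCL4L2 and CCL3L3 rose by 3.37 ± 0.61 and 3.06 ± 0.66. Their near-identical copies CCL4 and CCL3 rose by 2.92 ± 0.51 and 2.82 ± 0.61, and how reads divide between copies is uncertain. ACOD1, CCL4L2, CCL3L3 and CCL4 did not pass with no filter on low counts. The 12 genes of the rule were higher in 5 of 5 pairs, as the rule required. In PBS library A, GCKR stood at a log2 CPM of 5.08, against -2.79 to -0.90 in the other PBS libraries.

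The falls included genes of lysosomes, lipid uptake and the cell surface. FUCA1, a lysosomal fucosidase, had a log2 fold change of -5.25 ± 0.49 (SE, adjusted p = 6.78e-05), from 41.1 ± 35.7 CPM with PBS to 0.927 ± 0.618 CPM with rGal-1 (SD, n = 5). FPR3, a receptor of the formyl peptide family, stood at -5.03 ± 0.68, CD180, a Toll-like receptor homologue, at -4.63 ± 0.54, and the tetraspanin CD9 at -4.06 ± 0.49. NOTCH3 stood at -3.65 ± 0.48, the cholesteryl ester hydrolase NCEH1 at -3.42 ± 0.60, and OLR1, a receptor of oxidised low-density lipoprotein, at -3.29 ± 0.49. PPARG, a lipid-sensing nuclear receptor, stood at -3.25 ± 0.50, the secreted matrix protein TGFBI at -3.19 ± 0.37, OLFML2B at -3.13 ± 0.72 and GPAT3, an enzyme of triglyceride synthesis, at -3.13 ± 0.40. These genes and GPNMB were lower in 5 of 5 pairs, as the rule required. FUCA1, FPR3, CD9 and TGFBI also passed without the block (adjusted p = 0.0243 each). CD180, NOTCH3, PPARG and OLFML2B had no read in the shallow rGal-1 library C, and NCEH1 had none in rGal-1 library D. LGALS1, which encodes galectin-1, did not pass: its log2 fold change was -0.72 ± 0.22 (SE, adjusted p = 0.121), from 35.3 ± 11.6 CPM with PBS to 21.0 ± 5.19 CPM with rGal-1 (SD, n = 5), lower in 5 of 5 pairs.

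In the GENCODE annotation of GRCh38, IL6 lies on chromosome 7 from 22725884 to 22732002, GPNMB lies on chromosome 7 from 23235967 to 23275108, IL2RA lies on chromosome 10 from 6010689 to 6062370, and IL1A lies on chromosome 2 from 112773915 to 112784590. In the same annotation FUCA1 lies on chromosome 1 from 23845077 to 23868294, FPR3 lies on chromosome 19 from 51795163 to 51826189, TGFBI lies on chromosome 5 from 136028895 to 136063818, and LGALS1 lies on chromosome 22 from 37675608 to 37679806. All of these are annotated as protein-coding, and their values are read counts per gene symbol. CCL3L3 had no match in that annotation.

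**Figure D3:**
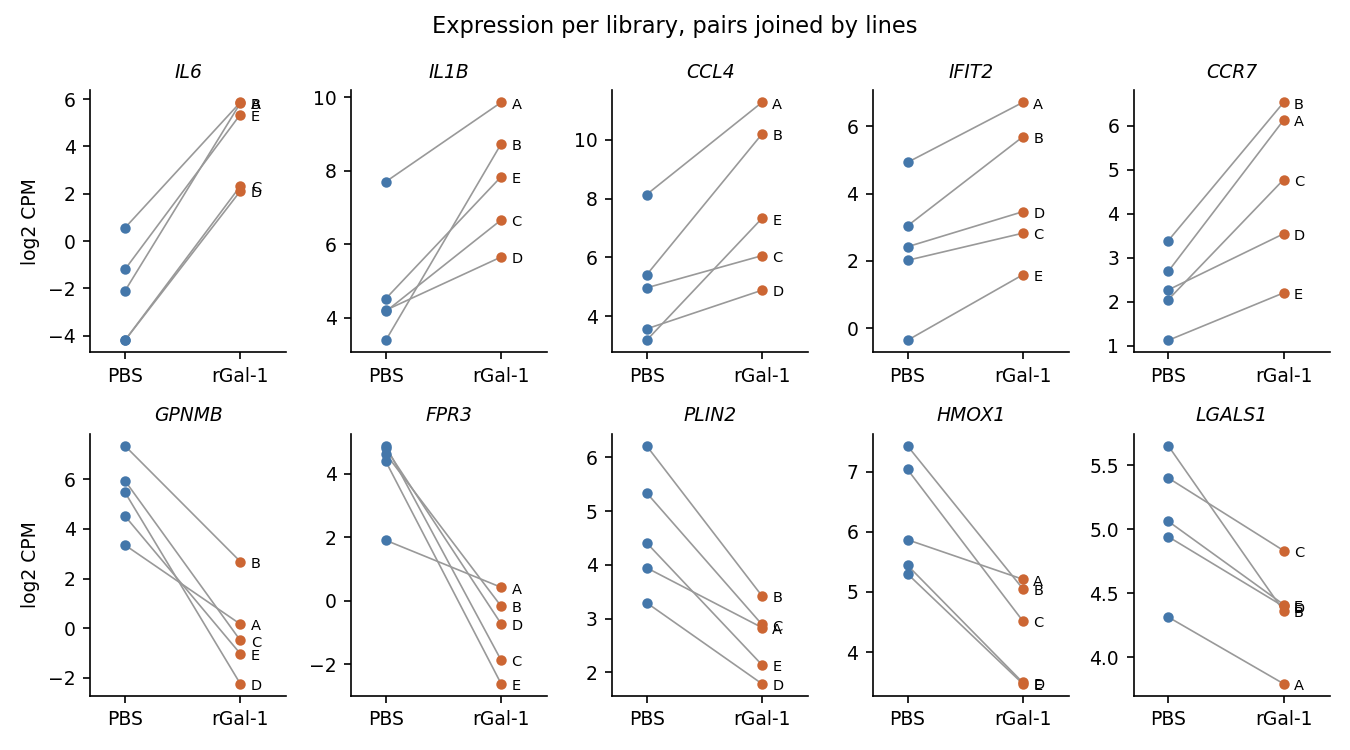
Log2 CPM of the genes shown, per library, with the PBS and the rGal-1 library of each pair joined by a line. IL6 rises and GPNMB falls in 5 of 5 pairs, while LGALS1 is lower in 5 of 5 pairs without passing the test.

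Proinflammatory cytokine genes were higher in part. Of 20 tested, 19 had positive fold changes, 8 rose, 1 fell and 11 did not pass, or 17 higher and 1 lower adjusted over the list alone. Besides IL6, IL1A and IL36G, CSF2, a myeloid growth factor, rose by 5.30 ± 0.79 (SE) and IL1B by 2.89 ± 0.45. CSF2 was higher in 4 of 5 pairs, with no read in 3 PBS libraries or in either library of pair C. TNFSF14, a tumor necrosis factor family ligand, stood at -1.54 ± 0.24. The list's median log2 fold change was 2.02 (camera adjusted p = 1.14e-12, and adjusted p = 0.497 with an estimated correlation). In PBS library A the list's mean log2 CPM was 1.45, against -0.50 to -0.03 in the other PBS libraries, and without pair A 5 members passed. Without the block 0 members passed.

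Chemokine genes were higher in part. Of 15 tested, 11 had positive fold changes, 7 rose, 0 fell and 8 did not pass, or 9 higher and 2 lower adjusted over the list alone. CXCL2, a neutrophil attractant, rose by 1.84 ± 0.27 (SE, adjusted p = 0.00259) and CCL5, a T cell attractant, by 1.77 ± 0.36. The median was 1.39 (camera adjusted p = 0.00138, and adjusted p = 0.530 with an estimated correlation). PBS library A had a mean log2 CPM of 5.06, against 1.85 to 2.68 in the other PBS libraries. The list's mean went from 2.68 with PBS to 2.69 with rGal-1 in pair C and from 2.03 to 1.91 in pair D, while it rose in pairs A, B and E. The count was 3 without pair A, 4 without pair B (3 higher and 1 lower), 2 without pair E and 0 without the block. DESeq2 and the fit with no filter on low counts also called 1 member lower each.

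NF-kB response genes, targets and regulators of a transcription factor of inflammation, had 5 of 30 members higher, 0 lower and 25 not past the test, or 17 higher adjusted over the list alone. TRAF1 rose by 1.69 ± 0.29 (SE), PTGS2, the inducible prostaglandin synthase, by 2.87 ± 0.51, TNIP3 by 2.88 ± 0.56 and TNFAIP6 by 2.73 ± 0.58. The median was 0.77 (camera adjusted p = 1.28e-07, and adjusted p = 0.530 with an estimated correlation). PBS library A had a mean log2 CPM of 4.81, against 3.24 to 3.64 in the other PBS libraries. The count was 3 without pair A, 2 without pair B, 0 without pair E, 11 without pairs C and D and 0 without the block.

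Interferon-stimulated genes had positive fold changes in 34 of 34 members, of which 9 passed and 25 did not, or 27 passed adjusted over the list alone. IFIT2 rose by 1.69 ± 0.29 (SE, adjusted p = 0.00561), IFIT3 by 1.74 ± 0.32, OAS2, a sensor of double-stranded RNA, by 1.42 ± 0.29, and ISG15, a ubiquitin-like protein, by 1.65 ± 0.35. The median was 1.24 (camera adjusted p = 1.14e-12, and adjusted p = 0.530 with an estimated correlation), and 1.87 without pairs C and D, in which the list's mean log2 CPM rose by 0.21 and 0.30. The count was 4 without pair A, 0 without pair B, 0 without pair E, 26 without pairs C and D and 0 without the block.

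Co-stimulation and maturation genes had 3 of 13 members higher, 0 lower and 10 not past the test, or 6 higher adjusted over the list alone. CCR7, which guides cells to lymph nodes, rose by 2.37 ± 0.36 (SE, adjusted p = 0.00276), TNFRSF9 by 2.01 ± 0.35 and CD83 by 0.94 ± 0.22, and CD83 did not pass with no filter on low counts. The median was 0.90 (camera adjusted p = 0.00169, and adjusted p = 0.530 with an estimated correlation), or 1.38 without pairs C and D, and the count was 1 without pair B, 7 without pairs C and D and 0 without the block. Immediate early and AP-1 genes had a median of 0.44 (camera adjusted p = 0.00918, and adjusted p = 0.530 with an estimated correlation). In that list EGR2, a transcription factor of myeloid cells, fell, at -1.30 ± 0.25, and 24 of 25 members did not pass, or 3 were higher and 2 lower adjusted over the list alone.

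**Figure D4:**
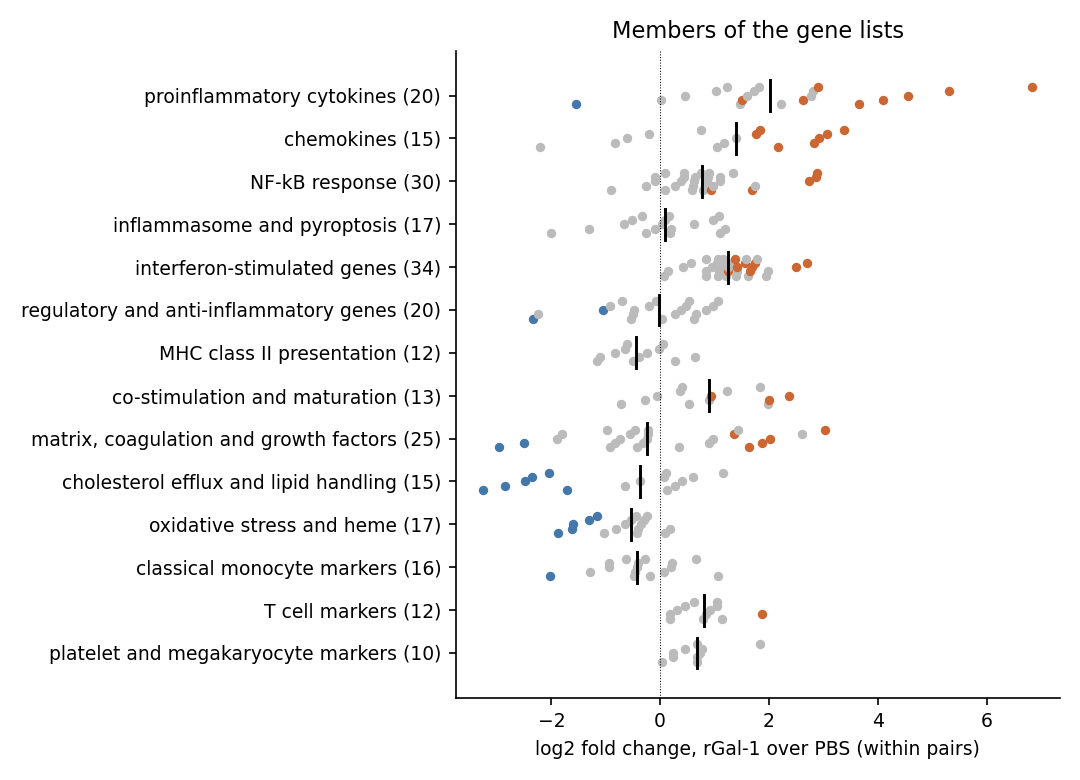
Log2 fold change of rGal-1 over PBS within pairs for the tested members of 14 gene lists, with the number tested in brackets and each list's median marked. Medians run from 2.02 for proinflammatory cytokines to -0.53 for oxidative stress and heme genes.

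Of 15 cholesterol efflux and lipid handling genes, 6 fell, 0 rose and 9 did not pass, and 7 had positive fold changes; adjusted over the list alone 7 were lower. PLIN2, a coat protein of lipid droplets, stood at -2.05 ± 0.28 (SE, adjusted p = 0.00149), the scavenger receptor CD36 at -2.49 ± 0.43 and the lysosomal cholesterol carrier NPC2 at -1.72 ± 0.29. The list's median was -0.36 (camera adjusted p = 0.0173, and adjusted p = 0.530 with an estimated correlation), against -0.07 without pair A (7 of 14 positive), -0.11 without pair B (4 of 14 positive) and -0.64 without pair E. The mean fold change was -0.86. The list's mean log2 CPM was lower after rGal-1 in each pair, with differences from -0.52 in pair E to -1.69 in pair C.

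Of 17 oxidative stress and heme genes, 5 fell, 0 rose and 12 did not pass, or 6 were lower adjusted over the list alone. HMOX1, which degrades heme, stood at -1.88 ± 0.28 (SE, adjusted p = 0.00285), CYBB, a subunit of the phagocyte oxidase, at -1.62 ± 0.26 and GCLC, an enzyme of glutathione synthesis, at -1.16 ± 0.25. The median was -0.53 (camera adjusted p = 0.000205, and adjusted p = 0.530 with an estimated correlation), against -0.81 without pair A, -0.34 without pair D and -0.14 without pairs C and D. Of 17 galectins and their glycan partners, LGALS3 at -2.12 ± 0.40 and LAMP2 at -1.45 ± 0.31 fell and 15 did not pass, or 4 were lower adjusted over the list alone. Their median was -0.37 (camera adjusted p = 0.0146, and adjusted p = 0.530 with an estimated correlation), against -0.57 without pair A and -0.23 without pairs C and D.

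Matrix, coagulation and growth factor genes moved both ways. Of 25 tested, 5 rose, 2 fell and 18 did not pass, or 6 were higher and 6 lower adjusted over the list alone. FN1, fibronectin, stood at -2.96 ± 0.37 (SE) and the protease inhibitor TIMP2 at -2.51 ± 0.33, while SERPINB9, an inhibitor of granzyme B, rose by 2.01 ± 0.33 and the membrane protease MMP14 by 1.63 ± 0.27. The median of -0.24 and the mean of 0.04 differ in sign (camera adjusted p = 0.874). The median was -0.48 without pair A, -0.43 without pair B, -0.14 without pair C, -0.02 without pair D and 0.18 without pairs C and D (17 of 29 positive). The count was 4 without pair B, 3 without pair E and 0 without the block. Of 20 regulatory and anti-inflammatory genes, the hemoglobin scavenger receptor CD163 at -2.34 ± 0.53 and ANXA1 at -1.05 ± 0.26 fell and 18 did not pass, or 4 were higher and 4 lower adjusted over the list alone (median -0.02, -0.17 to 0.39 with a pair left out, the low end without pair B and the high end without pair C, 0.54 without pairs C and D, 0.30 with no filter and 0.08 with DESeq2 size factors, camera adjusted p = 1.00). ANXA1 did not pass with DESeq2 size factors, CD163 had a log2 CPM of 3.41 in PBS library B against 0.82 to 1.51 in the other PBS libraries, and the count was 0 without pair B, 1 without pair D, 0 without pair E, 4 without pairs C and D and 0 without the block.

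Inflammasome and pyroptosis genes had 0 of 17 members past the test in edgeR, with 6 at an unadjusted p under 0.05, 4 calls by DESeq2 and 4 by limma-voom, or 2 higher adjusted over the list alone (median 0.09, -0.06 without pair A, 0.22 without pair C, 0.24 without pair D, 0.16 without pair E and 0.29 without pairs C and D, camera adjusted p = 0.615). NLRP3, a sensor of the inflammasome, had a log2 fold change of 1.10 ± 0.34 (SE, adjusted p = 0.12), and GSDMD, the pore-forming gasdermin, 1.07 ± 0.31 (SE, adjusted p = 0.0855). NLRP3 passed without pair C and without pairs C and D. MHC class II genes had 0 of 12 members past the test in edgeR, with 4 at an unadjusted p under 0.05, 0 calls by DESeq2 and 2 by limma-voom, or 0 adjusted over the list alone (median -0.45, -0.16 without pair C and -0.09 without pairs C and D with 6 of 12 positive, camera adjusted p = 0.177). HLA-DMA stood at -1.10 ± 0.38 (SE) and HLA-DRB1 at -0.83 ± 0.30 (SE), and HLA-DRB1, whose sequence varies between people and has near-identical copies, passed without pair A.

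Among the markers of other blood cells 1 T cell marker passed the test. All 12 T cell markers tested had a positive fold change, with a median of 0.81 (camera adjusted p = 0.00517, and adjusted p = 0.530 with an estimated correlation). Without pair C, where the list's mean log2 CPM rose by 1.98, the median was 0.46 with 10 of 12 positive, and without pairs C and D it was 0.49 with 9 of 12 positive; in pair E the mean fell by 0.40. IL7R, the interleukin-7 receptor, rose by 1.88 ± 0.32 (SE), and 11 members did not pass, with the same count of 1 adjusted over the list alone. All 10 platelet and megakaryocyte markers were positive, with a median of 0.68 (camera adjusted p = 0.00723, and adjusted p = 0.530 with an estimated correlation), or 0.38 without pair B, and 0 passed in edgeR, 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma-voom. NK cell markers had a median of 0.30 over 7 members and B cell markers of 0.61 over 3, with 0 members past the test in edgeR in each. Adjusted over the list alone, 2 NK cell markers were higher and 1 lower, and 4 were at an unadjusted p under 0.05, with 3 calls by DESeq2 and 3 by limma-voom; for B cell markers these counts were 0, 0, 0 and 1. With a pair left out the medians were 0.02 to 0.63 and 0.44 to 1.11, and without pairs C and D -0.17 (3 of 8 positive) and 0.27 (4 of 6 positive).

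Of 16 classical monocyte markers CYP1B1, an oxidising enzyme, fell, at -2.02 ± 0.37 (SE), and 15 did not pass, or 1 was higher and 2 lower adjusted over the list alone (median -0.42, -0.22 without pair B, -0.25 without pair C and -0.26 without pair E, camera adjusted p = 0.196). CD14, the surface marker used for the enrichment, stood at -0.94 ± 0.34 (SE, adjusted p = 0.196). Of 13 non-classical monocyte markers CSF1R, a growth factor receptor, at -1.98 ± 0.46 and the integrin chain ITGAL at -1.15 ± 0.28 fell, and 4 were lower adjusted over the list alone (median -0.31, -0.19 without pair C, -0.49 without pair D and -0.62 without pairs C and D, camera adjusted p = 0.196). ITGAL did not pass with DESeq2 size factors, and CSF1R had a log2 CPM of 3.11 in PBS library A, against 5.68 to 6.28 in the other PBS libraries.

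Of the 34 lists, 11 passed camera with the preset correlation, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.0518. Without pairs C and D, the named genes GCKR, ANXA1, LAMP2, CYP1B1, CSF1R and PKM did not pass, while CD14 did. Of the lists not yet described, none passed, and the smallest camera adjusted p was 0.0535, for heat shock genes (median 0.27, 0.16 to 0.43 with a pair left out, and 0.54 without pairs C and D with 16 of 18 positive). The ranges after the other medians are likewise with a pair left out. In the glycolysis and hypoxia list (median -0.13, -0.36 to 0.06) PKM, a glycolytic kinase, fell, at -1.22 ± 0.29 (SE), though not with DESeq2 size factors, and in the sterol synthesis list (median -0.20, -0.24 to 0.04, mean 0.03, and a median of 0.19 without pairs C and D with 10 of 17 positive) LSS rose by 1.57 ± 0.32. In edgeR 0 members passed among Toll-like receptor genes (median -0.38, -0.51 to -0.08; 3 of 17 at an unadjusted p under 0.05, 0 calls by DESeq2 and 1 by limma-voom), JAK-STAT genes (median 0.05, 0.06 to 0.21; 7 of 26, 4 calls by DESeq2 and 8 by limma-voom), metallothioneins (median 1.01, 0.53 to 1.62; 2 of 5, 0 and 3 calls), apoptosis genes (median 0.27, 0.18 to 0.33; 3 of 20, 1 and 4 calls), heat shock genes (3 of 18, 3 and 3 calls) and cell cycle genes (median 0.50, 0.25 to 0.53, and -0.02 without pairs C and D; 0 of 9, 0 and 0 calls).

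The same held for the remaining marker lists, in which edgeR called 0 members. Dendritic cell markers had a median of 0.18 (-0.12 to 0.31 with a pair left out) and 1 of 6 at an unadjusted p under 0.05 (1 call by DESeq2 and 2 by limma-voom), and basophil and mast cell markers a median of -0.33 (-0.62 to 0.03), a mean of 0.22 and 1 of 3 (1 call by DESeq2 and 1 by limma-voom). Without pairs C and D the median of the basophil and mast cell markers was 0.73 (2 of 4 positive). Mature neutrophil markers (median 0.17, -0.41 to 0.42, mean -0.12), immature granulocyte markers (0.02, -0.23 to 0.65), erythroid markers (0.30, 0.02 to 0.75), progenitor markers (1.20, 1.00 to 1.86) and stromal and endothelial markers (0.01, -0.27 to 0.51) had 0 members at an unadjusted p under 0.05 and 0 calls by DESeq2, with 2 erythroid markers called by limma-voom and 0 of the other 4 lists. The erythroid median was 1.03 (8 of 8 positive) and the progenitor median 0.72 (3 of 3 positive) without pairs C and D.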

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

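Within each arm, the library farthest from the others was compared with the spread of the 5 for 248 measures: library qualities, list means and the genes examined singly. In 12 of them 1 library stood apart from the other 4 by more than a test for a single outlying value allows at the 95% level. For independent measures chance does so in about 1 of 20. The 248 measures are not independent, so the count of 12 cannot be judged against that rate. Of the 12, 10 were in PBS library A, and they are not independent of each other, since they share that library. No biological explanation was tested for them.

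PBS library A had high levels of inflammatory genes. Its mean log2 CPM was 1.45 over the proinflammatory cytokines (other PBS libraries -0.50 to -0.03), 5.06 over the chemokines (1.85 to 2.68) and 4.81 over the NF-kB response genes (3.24 to 3.64). In that library IL1B stood at a log2 CPM of 7.71 (3.39 to 4.52), CSF2 at -0.58 (-4.19 to -3.29), LINC00158 at 2.09 (-4.19 to -3.47), GCKR at 5.08 (-2.79 to -0.90) and AHRR at 4.72 (2.14 to 2.50). FPR3 was low there, at 1.91 (4.39 to 4.88), as was CSF1R, at 3.11 (5.68 to 6.28).

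In PBS library B, CD163 stood at a log2 CPM of 3.41, against 0.82 to 1.51 in the other PBS libraries. Among the rGal-1 libraries, TGFBI stood at 2.13 in library E, against 3.53 to 3.91 in the others.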

How the results depend on the processing

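Mitochondrial genes left out, pairs C and D left out and dispersions without the robust option were tested only after the data were seen, and the cause of the differences below was not tested unless named. The 6 genes called without the block were 58 with no filter on low counts, 55 with DESeq2, 321 with the replicate block, 11 at an adjusted p under 0.1, 0 without pairs C and D, which leaves fewer samples, and 0 to 6 when a pair or a library was left out. The 321 genes called with the pair block were 536 with no filter, 815 with DESeq2 and 1455 with limma-voom, of which 310, 321 and 316 were among the 321. They were 520 at an adjusted p under 0.1, 120 against a log2 fold change of 0.5, 6 without the block, and 77 to 323 when a pair or a library was left out. With DESeq2 size factors 286 genes passed (270 shared), with a CPM of at least 1 in 5 libraries 316, with mitochondrial genes left out 304, with the pair as a random effect 278 (215 shared) and without robust dispersions 327.

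Members called per list moved as follows. Proinflammatory cytokines had 9 and then 16 with DESeq2, 16 with limma-voom and 5 to 10 with a pair left out. Chemokines had 7 and then 2 to 7 with a pair left out. NF-kB response genes had 5 and then 14 with DESeq2, 18 with limma-voom, 11 without pairs C and D and 0 to 5 with a pair left out. Interferon-stimulated genes had 9 and then 21 with no filter, 20 with DESeq2, 28 with limma-voom, 26 without pairs C and D and 0 to 12 with a pair left out. Regulatory genes had 2 and then 5 with no filter, 7 with DESeq2, 8 with limma-voom, 4 without pairs C and D and 0 to 3 with a pair left out. Co-stimulation genes had 3 and then 6 with DESeq2, 8 with limma-voom, 7 without pairs C and D and 1 to 4 with a pair left out. Matrix genes had 7 and then 11 with limma-voom and 3 to 8 with a pair left out. Inflammasome genes had 0 and then 4 with DESeq2, 4 with limma-voom, 1 without pairs C and D and 0 to 1 with a pair left out. MHC class II genes had 0 and then 2 with limma-voom and 0 to 1 with a pair left out. Without the block all 9 of these lists had 0.

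Of the list tests 11 passed, against 0 with an estimated correlation, 0 with fry in 1 direction, 18 with fry in either direction (9 shared) and 11 without the block (10 shared). For the mitochondrial share an exact unpaired test gave p = 0.786 (n = 5); the test within pairs cannot pass with 5 pairs. None of the 85 genes examined singly, 77 of them named in the text, changed direction in a setting that tested it (82 were tested without pair A, 84 without pair B, 78 with a CPM of at least 1 in 5 libraries and 85 otherwise). Many of these genes were picked for a small p or for the same direction in all 5 pairs, so reversals were unlikely beforehand. Of those tested, 36 lost their call without pair E, 31 without pair B, 12 without pair A, 12 without pair C, 11 without pair D, 8 without pairs C and D, 5 with no filter, 4 with DESeq2 size factors, 2 with limma-voom and 0 with DESeq2. GCKR did not pass with limma-voom, without pairs C and D, without pair B or without pair E, and LGALS1 passed with limma-voom alone among these settings. Depth limits low levels: in the shallowest library a count of 0 allows up to 0.329 CPM. In simulated data 13 of 100 changes of 1 on the log2 scale were found with the block, and what limits that share was not tested.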

Other observations

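The gene lists added in this part, the test of monocyte loss, the separate tests of agreement for higher and lower calls and the test without pairs C and D were chosen after the results were seen; the other tests were set before. Because some members of the added lists had been seen to change, no test across a list is given. Of 46 lysosomal genes tested, 12 fell, 0 rose and 38 had negative fold changes, with a median of -0.67. PLBD2 stood at -2.48 ± 0.32 (SE) and the cathepsins CTSD and CTSB at -2.48 ± 0.34 and -1.87 ± 0.29, and of the 34 members not called 26 were negative, with a median of -0.36. Of 15 subunits of the vacuolar ATPase, which acidifies lysosomes, 3 fell, among them ATP6V1C1 at -1.77 ± 0.38, with a median of -0.72, or -0.65 over the 12 not called. The lysosome list shared 7 genes with the lists set before the data were examined and the ATPase list 0. ATP6V1C1 did not pass without pairs C and D.

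In a list of 6 genes of the aryl hydrocarbon receptor, a sensor of aromatic compounds, and its targets, CYP1A1 at -2.37 ± 0.42 (SE), CYP1B1 at -2.02 ± 0.37 and AHRR at -2.01 ± 0.39 fell. The list's median of -1.37 rests on these 3, which were seen before the list was written; the 3 not called had a median of -0.42. Of 14 chemoattractant and complement receptors 5 fell and 0 rose, among them FPR3, C5AR1 at -2.25 ± 0.34 and CCR1 at -1.81 ± 0.28, with a median of -0.87, or -0.54 over the 9 not called, of which 7 were negative. A list of 20 endotoxin-induced genes had 15 higher, 0 lower and a median of 2.78; 18 of the 20 are in lists set before, and since its members were picked from genes seen to rise, it is not independent evidence.

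The 135 higher calls, with inflammatory genes among them, and the 186 lower calls were weighed against causes other than galectin-1. GC content and transcript length were not the whole cause: after subtracting their trend the median of the lower calls was -1.61, from -1.67, and of the higher calls 1.87, from 1.84 (316 of 321 calls had a value). A higher mitochondrial share as the whole cause would reverse the calls in pair A, where the share fell. Of the 263 genes called without pair A, 84.0% (Wilson 95% interval 79.1% to 88.0%) kept their direction there. For the 84 higher calls it was 96.4%, and for the 179 lower calls 78.2% (71.6% to 83.6%). These values argue against that cause, more weakly for the lower calls. They rest on 1 pair, and the Wilson intervals here take genes as independent. The shallow pairs C and D were not the whole source of the calls: the fit of pairs A, B and E alone called 282 genes higher and 143 lower, of which 110 and 107 are among the 135 and 186, and its median for the proinflammatory cytokine list was 2.12 (bootstrap 95% interval 1.78 to 3.61). The bootstrap intervals here and below resample genes as if independent, so they do not measure the spread between samples. The lists set before the data were examined that passed camera with a fall were weaker in the fit of pairs A, B and E: -0.14 (-0.64 to 0.02), from -0.53, for oxidative stress and heme genes, -0.23 (-0.80 to 0.13), from -0.37, for galectins and their partners and -0.27 (-2.05 to 0.33), from -0.36, for lipid handling, so a share of C and D in those falls stays open. Lists with a negative median that did not pass camera moved both ways. Non-classical monocyte markers went to -0.62, from -0.31, and MHC class II genes to -0.09, from -0.45. Whether shallow depth or a weaker response lowers the agreement of C and D stays open: of the 425 genes called in pairs A, B and E, 400 were also tested with all pairs, and 79.0% of these (Wilson 95% interval 74.7% to 82.7%) kept their direction in C and D, 70.9% of 261 higher calls (65.1% to 76.1%) and 94.2% of 139 lower calls (89.1% to 97.1%). Endotoxin carried by the recombinant protein stays open beside an effect of galectin-1 itself, which was not tested apart from it. The interferon-stimulated genes, which endotoxin would raise, had a median of 1.24 (bootstrap 95% interval 1.07 to 1.42, which takes the members as independent though they correlate by 0.54). That list did not pass with an estimated correlation (adjusted p = 0.530), had 0 calls without pair B or without pair E, and its mean rose by 0.21 and 0.30 in pairs C and D, against 1.18 to 2.22 in the others.

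The lower calls and the T cell markers were also weighed against the mix of cells. Whether a loss of monocytes caused the lower calls could not be decided. The classical monocyte markers had a median of -0.42 (bootstrap 95% interval -0.67 to 0.07), above that of the lower calls at -1.67 (-1.77 to -1.51). The lower calls were picked by passing the test, which called no absolute log2 fold change under 0.91. Their larger fall was thus likely beforehand, and the values show only that these markers fell less than the called genes. The marker median was -0.22 without pair B, -0.25 without pair C and -0.26 without pair E. A lower share of monocytes also stays open when judged by the other cells. The medians of T, B and NK cell markers were 0.81, 0.61 and 0.30, and the interval for NK cells, -0.33 to 1.05, covers both no change and a like rise. These medians depend on single pairs: for T cells 0.46 without pair C, for B cells 0.91 without pair D and 1.11 without pair E, and for NK cells 0.02 without pair B, 0.61 without pair A, 0.51 without pair D and 0.63 without pair E. Without pairs C and D they were 0.49 (bootstrap 95% interval 0.00 to 0.94), 0.27 (-0.34 to 1.09) and -0.17 (-0.92 to 0.94, 3 of 8 positive) for T, B and NK cells, whose intervals overlap. The most abundant T cell marker, IL7R, went from 6.21 ± 3.12 CPM with PBS to 30.0 ± 24.2 CPM with rGal-1, and the CD14 bead enrichment selects against T cells. IL7R was the only 1 of 12 T cell markers to pass, and which cells its reads came from cannot be told from these libraries.

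The 6 genes called without the block were set against other splits of the 10 libraries into 5 and 5. Of 100 splits drawn from 126, 5 gave at least 6 genes, the real one included, and the highest of the others gave 90, so chance cannot be excluded for that count. The split with 90 kept both libraries of pairs A and B and 1 of pair E on the same side, which points to a structure of the samples. In 5 drawn splits all 4 libraries of the shallow pairs C and D were on the same side. Of these, 3 gave 90, 57 and 7 genes and 2 gave 0. Another split, with PBS library A and rGal-1 libraries A, B, C and E on the same side, gave 26. It is the real split with PBS library A and rGal-1 library D exchanged, so its genes can carry the treatment difference. Whether pairs C and D are the whole source of the structure thus stays open. For their part depth, mitochondrial share and the samples cannot be told apart. None of the 15 drawn splits other than the real one that part all 5 pairs gave a gene (highest 0). For the 321 genes of the fit with the pair block there are 16 splits within pairs, too few for a share under 0.05; 1 of the 16, the real one, gave 321 genes and the highest of the others gave 0.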
